A study of Mus musculus with 3 samples.

How the data were processed

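Gene expression was measured in mouse embryonic stem (ES) cells, pluripotent cells derived from the early embryo, in a study of overexpression of the transcription factor Gata6. Per the series' design text, cells had been modified so that the overexpression responds to dex, read here as dexamethasone, a synthetic glucocorticoid. Whether the day 0 control cells carried the modification and lacked only dex is not given in the sources used here. The labels place 1 array each at day 0 (the control), day 1 and day 2, so there are 3 arrays and no replicates. Per the labels' protocols, total RNA was extracted with Trizol, cleaned on columns, and turned into biotinylated cRNA with an Affymetrix one-cycle kit. The dose of dex and its timing are not given in the sources used here.

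The deposited values are linear intensity values per probe set, summarised with MAS5 per the submitters' processing notes, in which no version is named. MAS5 combines the perfect-match and mismatch probes of a probe set into 1 signal. The 3 columns had medians of 84.2 (day 0), 81.8 (day 1) and 86.4 (day 2), and 2% trimmed means of 497.5, 497.6 and 497.7, so a common scaling had been applied before deposit. Its target is not stated in the labels. The values carry no log and no centring per probe set. A global scaling of this kind assumes that total signal did not differ between the days.

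The table held 45101 probe sets, of which 64 were controls. Of the other 45037, 34945 were annotated to 1 gene, 932 to several genes and 9160 to none, the last being unnamed here. Symbols came from the platform annotation and were looked up by gene identifier in a RefSeq gene table of assembly GRCm38.p6, used for names only; 34741 of the 34945 probe sets matched. Probe sets with several genes were left out of every gene result. No column of the table went unused.

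Each array was scaled to the same 2% trimmed mean over probe sets that were not controls. Values under a floor of 54.0, the 40th percentile of all scaled values, were then set to the floor, and log2 was taken. Each gene was represented by the probe set with the highest mean log2 value over the 3 arrays, which gave 18193 genes, 14257 of them above the floor on at least 1 array. A gene was counted as higher or lower where 2 arrays differed at least 2-fold and the brighter one lay above the floor. Where the dimmer array was at the floor, the fold is a lower bound and is written as at least N-fold. The same wording is used for genes whose dimmer signal lay above the floor but under the receptor background given below, with the fold taken against that signal, a choice made after the values were seen.

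With 1 array per day no test between days was possible, and no p-value is given. The only error estimate came from genes with several probe sets: the SD of the difference in log2 ratio between 2 probe sets of a gene, divided by the square root of 2. It was 0.37 over 19454 pairs from the 3 comparisons, 0.50 for signals under 200, 0.38 from 200 to 1000, 0.23 from 1000 to 5000 and 0.15 over 5000. It covers measurement within a pair of arrays and not the spread between cultures, and the number of arrays limits the precision. Probe sets for olfactory and vomeronasal receptors, genes that ES cells should not express, served as background. Their 95th percentile was 70.2. Of the 80, most were at the floor on both arrays of a comparison and could not differ. Among those above it on at least 1 array, 0 of 14 differed at least 2-fold in day 1 against day 0, 2 of 18 in day 2 against day 0 and 1 of 15 in day 2 against day 1.

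The comparisons, the floor, the fold threshold, 20 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The lists covered primitive, parietal and visceral endoderm, basement membrane, pluripotency, primed epiblast, trophectoderm, mesoderm, neural ectoderm, Hox genes, Polycomb components, epithelial and mesenchymal genes, glucocorticoid response, FGF and ERK signalling, cell cycle, fibroblasts, housekeeping, 2-cell-like cells, glycolysis and cholesterol synthesis. They held 495 different genes, of which 451 were on the array and 392 were measured, that is above the floor on at least 1 array. A list's median log2 ratio is given with its percentile among 10000 random lists of the same size, matched on mean log2 value in 20 bins. That percentile describes these arrays and is no test of the conditions. Named genes were the 10 highest and 10 lowest in each comparison among genes whose probe sets above the floor had the same sign, the 3 members of each list with the widest difference at day 2 against day 0, and Gata6, Gata4, Sox7, Sox17, Dab2, Pou5f1, Nanog, Sox2, Ring1 and Rnf2. This made 102 genes. Other list members are named as examples and were chosen after their values were seen.

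Day 1 and day 2 share the day 0 array. Their agreement was therefore set beside 100 simulated sets of 3 arrays with no change, whose noise came from the probe set differences. That noise was estimated only from probe sets above the floor on both arrays and holds no spread between cultures. The simulated counts may therefore be too low. The calling step was tested on simulated data for day 2 against day 0 with 18193 genes, 200 of them changed. All 200 were drawn from genes more than 2-fold above the floor on the 3 real arrays, so recovery of dimmer genes was not tested. The step recovered 96% of the 3-fold changes in each direction, 100% of the 4-fold higher and 96% of the 4-fold lower genes, and 100% of the 8-fold and 16-fold ones. Of 17993 unchanged genes, 254 were called. Genes under the floor throughout could not be called, and 13293 of the 18193 lay above it on at least 1 simulated array. A list shifted by 0.5 in log2 ranked at percentile 100, and 7 of 100 random lists fell outside the central 95% range.

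The alternatives were 4 other scalings (values as deposited, quantile, loess, and centring on the median of bright probe sets), floors at the 25th and 60th percentile and at the receptors' 95th percentile, a pseudocount of 7.10 with no floor, the mean over a gene's probe sets, leaving out probe sets whose names mark them as unspecific, and a 3-fold threshold. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used. The comparison with other experiments that the design text mentions was not analysed here.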

Results

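The data set describes mouse ES cells at day 0, 1 and 2 of overexpression of Gata6, a zinc finger transcription factor of the primitive endoderm, the extraembryonic layer that lines the early embryo. A single array was hybridised for each of day 0, day 1 and day 2. The values have no replicates, so a difference between days is also a difference between single cultures and arrays. The labels do not say whether the day 0 control cells carried the Gata6 modification, so a ratio against day 0 can also include a difference between cell populations. The median signal was 84.2 on day 0, 81.8 on day 1 and 86.4 on day 2, and 12657, 12289 and 12646 genes lay above the floor of 54.0. The ratio of 3' to 5' signal of the Actb control probe sets, a sign of RNA integrity, was 1.25, 1.21 and 1.24, and that of Gapdh was 0.784, 0.766 and 0.765.

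Gata6 itself was compared first. Its signal was 109.6 on day 0, 5574 on day 1 and 6069.6 on day 2, which is 50.8-fold and 55.4-fold higher than on day 0. Another Gata6 probe set read 177, 3769 and 4316, and the third stayed dim at 4.90, 50.4 and 103. Whether these probe sets detect the introduced Gata6, the cell's own gene or both was not settled here.

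The first comparison, day 1 against day 0, asks which genes differed within a day of Gata6 overexpression. Endoderm genes were far brighter on day 1. Pdgfra, a growth factor receptor of the primitive endoderm, was at least 173-fold higher, the proteoglycan Srgn at least 164-fold, the endocytic adaptor Dab2 152-fold and the transcription factor Sox17 at least 140.5-fold. Pluripotency genes were dimmer, with Nanog 4.25-fold, Sox2 4.34-fold and Pou5f1 (Oct4) 2.71-fold lower. In all, 816 genes were at least 2-fold higher and 895 at least 2-fold lower of 13602 compared.

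Of 24 measured primitive endoderm regulators, 18 were higher on day 1 and 0 lower, with a median log2 ratio of 2.48 (percentile 100 among matched random lists, whose central 95% range was -0.24 to 0.22). The overexpressed gene, Gata6, is on this list and counts among its higher members on day 1 and day 2. Gata4 read 54.0 (the floor), 1545 and 2747 on the 3 days, and Sox7 read 54.9, 1501 and 1959. A second Sox7 probe set stayed low at 7.30, 89.6 and 59.7. The forkhead factor Foxq1 was at least 55.4-fold and the secreted signal Bmp2 at least 54.9-fold higher. Further genes among the 10 highest were the Wnt inhibitor Dkk1 (73.0-fold), the adhesion protein Flrt3 (at least 76.0-fold), the Fgf co-receptor Klb (at least 62.2-fold) and Amot (62.5-fold). The 3 Amot probe sets had log2 ratios from 0.96 to 5.97, those of Dkk1 from 3.12 to 6.19 and those of Pdgfra from 4.23 to 7.44.

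Basement membrane genes were higher as a group already on day 1: 11 of 22 were higher and 2 lower, with a median log2 ratio of 0.96 (percentile 100). The laminin chain Lamb1 was 33.3-fold and the collagen chaperone Serpinh1 44.0-fold higher. The 4 Lamb1 probe sets had log2 ratios from 2.02 to 5.46. The 2 lower members were Fn1 (log2 ratio -2.29) and Col18a1 (-1.93). Of 14 parietal endoderm genes, which mark the migratory cells that lay down this membrane, 10 were higher and 1 lower, with a median of 1.98 (percentile 100). Some of these genes stand on more than 1 list, Lamb1, Sparc, Sox7 and Pth1r among them.

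Of the 50 measured pluripotency genes, 24 were lower and 0 higher on day 1, with a median log2 ratio of -0.87 (percentile 0, random range -0.14 to 0.10). Eras, an ES cell Ras protein, was 15.3-fold lower and the growth factor Fgf4 11.7-fold. FGF and ERK signalling genes had a median of -0.68 (percentile 0), with 6 of 21 higher and 7 lower. The lower ones included Dusp6, a phosphatase of the ERK pathway, at 9.32-fold, while the receptors Fgfr2 (log2 ratio 2.60) and Fgfr3 (2.19) were higher. The gene with the lowest ratio was Trh, which encodes thyrotropin-releasing hormone, at 2079.7 on day 0 and at the floor on day 1, at least 38.5-fold lower. The amino acid transporter Slc7a3 (11.6-fold), the activin subunit Inhbb (12.1-fold), 1700019D03Rik (12.5-fold) and Enox1 (at least 12.2-fold) were also lower, as were Bnc2 (at least 11.8-fold) and Crtac1 (at least 11.2-fold), which were at the floor on day 1. Cpsf4l was at least 14.4-fold lower on an unspecific probe set and had a log2 ratio of -0.66 on its specific one.

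Probe sets of 1 gene mostly had the same sign. Of the genes with several probe sets above the floor, this held for 360 of 428 higher and 334 of 384 lower genes. Simulated arrays with no change gave a mean of 117 higher and 116 lower genes, with ranges of 90 to 145 and 90 to 138. These hold measurement noise only, without the spread between cultures, so they are no full count of false calls. The counts moved with the floor, to 1256 higher and 1618 lower at the 25th percentile and to 539 and 517 at the 60th.

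**Figure D1:**
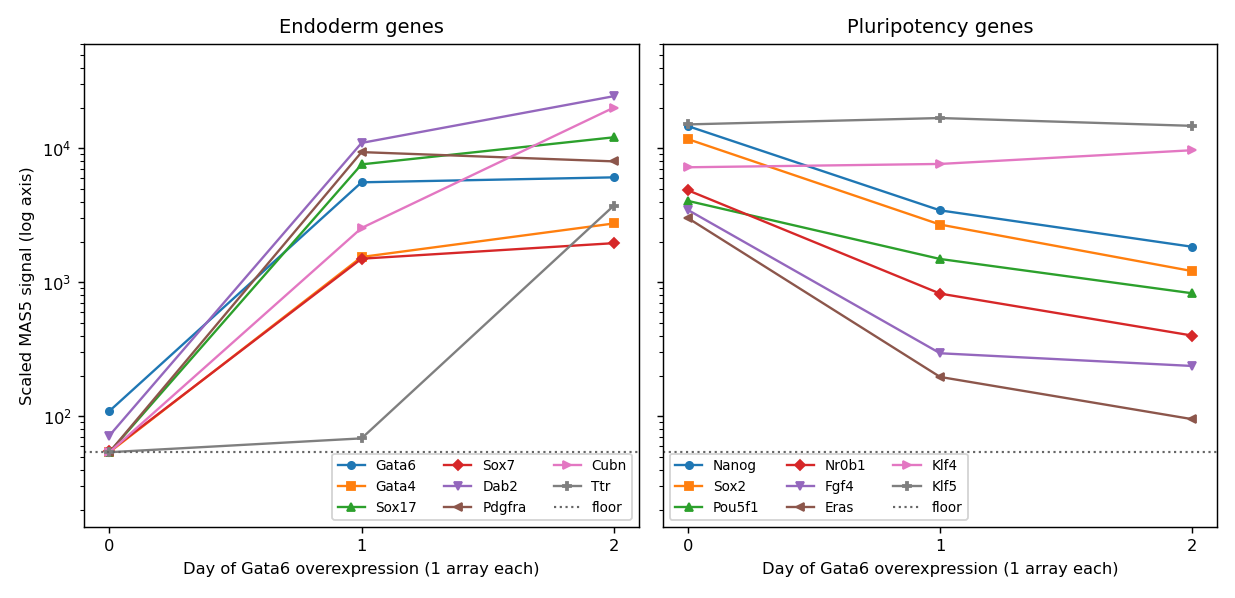
Scaled MAS5 signal on a log axis against day for 8 endoderm genes and 8 pluripotency genes, with 1 point per array and the floor of 54.0 as a dotted line. Pdgfra read 9365 on day 1 and 7986 on day 2, Ttr stood at 68.5 on day 1 and 3728 on day 2, and Klf4 and Klf5 stayed within 2-fold of day 0.

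The second comparison, day 2 against day 0, asks how far expression differed after a further day. Endoderm genes were again far brighter, among them more markers of visceral endoderm, the absorptive and secretory layer around the embryo. Srgn was at least 448-fold higher than on day 0, the endocytic receptor Cubn at least 372-fold, Dab2 340.2-fold, Sox17 at least 224-fold and Pdgfra at least 148-fold. Nanog was 7.95-fold, Sox2 9.65-fold and Pou5f1 4.89-fold lower. Of 13865 genes compared, 1532 were at least 2-fold higher and 1399 at least 2-fold lower.

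Primitive endoderm regulators were higher in 21 of 24 cases and lower in 0, with a median log2 ratio of 4.49 (percentile 100). The parietal endoderm list had 12 of 14 genes higher and 1 lower, with a median of 3.89 (percentile 100; 2.73 with means over probe sets and 3.28 with the floor at the 60th percentile). The parathyroid hormone receptor Pth1r was at least 81.6-fold and the trafficking protein Nostrin at least 48.7-fold higher, whereas the lower member was the intermediate filament gene Vim (log2 ratio -1.72). Basement membrane genes had a median of 1.53 (percentile 100), with 14 of 22 higher and 2 lower. Serpinh1 was 71.1-fold, Lamb1 42.5-fold (log2 ratios from 2.26 to 6.44 over its probe sets) and the collagen prolyl hydroxylase subunit P4ha2 37.9-fold higher. Others among the 10 highest were Klb (at least 135-fold), the heparan sulfate enzyme Hs3st1 (at least 105-fold), Flrt3 (at least 104-fold), Amot (87.0-fold) and Foxq1 (at least 83.0-fold).

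Of 24 measured visceral endoderm genes, 13 were higher and 2 lower on day 2, with a median log2 ratio of 1.09 (percentile 100). On day 1 the numbers had been 8 and 4, with a median of 0.14 (percentile 98.1). The thyroid hormone carrier Ttr was at least 69.0-fold higher, and the lipid transfer protein Mttp read 61.3, 245 and 1226 on the 3 days. The apolipoproteins Apoa1, Apob and Apoc2 were at or near the floor on each array, with highest signals of 56.6, 65.7 and 63.3. With the floor at the 60th percentile the day 1 and day 2 medians were 0.00 and 0.51, and with a pseudocount in place of the floor 0.50 and 2.00.

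The pluripotency list had 33 of 50 genes lower and 0 higher, with a median of -1.79 (percentile 0). Eras was 31.6-fold and the orphan receptor Nr0b1 12.1-fold lower, and Fgf4 14.6-fold. The other 17 genes were within 2-fold of day 0. Klf4 read 7216, 7641 and 9672 on the 3 days, Klf5 read 15070.5, 16813 and 14701, and Sall4 read 8058, 11337 and 10794. Sall4 is also on the list of primitive endoderm regulators. FGF and ERK signalling genes had a median of -0.87 (percentile 0), with 5 of 21 higher and 10 lower: Dusp6 was 20.3-fold and the transcription factor Etv4 at least 16.4-fold lower. With each gene taken as the mean over its probe sets, the median of this list was -0.55. Other genes among the 10 lowest were the Hedgehog effector Gli2 (26.5-fold), Rasgrp2 (at least 30.0-fold), Tcea3 (at least 27.6-fold), Inhbb (at least 23.1-fold), Calml4 (at least 22.7-fold), Pcolce (22.3-fold), Morc1 (21.1-fold) and Mymx (20.6-fold). The Rasgrp2 probe sets had log2 ratios from -4.908 to -1.195.

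Markers of other embryonic lineages were compared next. Of 17 mesoderm and primitive streak genes, 1 was higher and 3 lower on day 2, with a median of -0.05 (percentile 35.3), and on day 1 0 were higher and 2 lower, with a median of 0.00. The lower ones included Bmp4 (18.6-fold), which read 4682 on day 0, and Meox1, which read 162 on day 0 and was at the floor on the other days. The higher one, Foxf1, read 154 on day 2 and had a log2 ratio of 0.27 as a mean over its probe sets. Neural ectoderm genes had a median of 0.00 on both days, with 2 of 17 higher and 2 lower on each. Tubb3 was 7.39-fold and Gbx2 at least 9.16-fold lower, and Irx3 was at least 5.00-fold higher. Of 16 measured Hox genes, 3 were higher and 1 lower on day 2, with a median of 0.20 (percentile 94.9), and 0 differed 2-fold on day 1 (median 0.06). The day 2 Hox median was 0.73 with the floor at the 25th percentile and 0.90 with a pseudocount, and the day 1 neural median -0.32 and -0.30. Hoxd8 at 187, Hoxd9 at 137 and Hoxc9 at 54.4 were all dim on day 2. With the floor at the 60th percentile, Meox1, Foxf1, Irx3, Hoxd8, Hoxd9 and Hoxc9 all differed less than 2-fold.

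Primed epiblast genes, which mark the later pluripotent state, had a median of -0.67 on day 1 (percentile 0.03, 4 of 14 higher and 5 lower) and 0.00 on day 2 (percentile 59.1, 2 higher and 6 lower). Otx2 was 11.5-fold and Nodal 9.78-fold lower on day 2. The tight junction gene Cldn6, higher on day 2 by 32.2-fold, is on this list and on the epithelial one. The day 1 median of the list was 0.00 with the floor at the 60th percentile.

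Trophectoderm genes had a median of 0.28 on day 1 (percentile 99.4, 6 of 24 higher and 6 lower) and 0.72 on day 2 (percentile 99.98, 10 higher and 5 lower). Those medians depended on the probe sets used. With unspecific probe sets left out they were -0.07 and 0.00, and with the floor at the 60th percentile both were 0.00. The members with the widest differences were Bmp4 and Esrrb (9.60-fold lower), and the keratin Krt8, which was 9.46-fold higher and is also on the epithelial list. Cdx2, a trophectoderm regulator, reached 121.

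**Figure D2:**
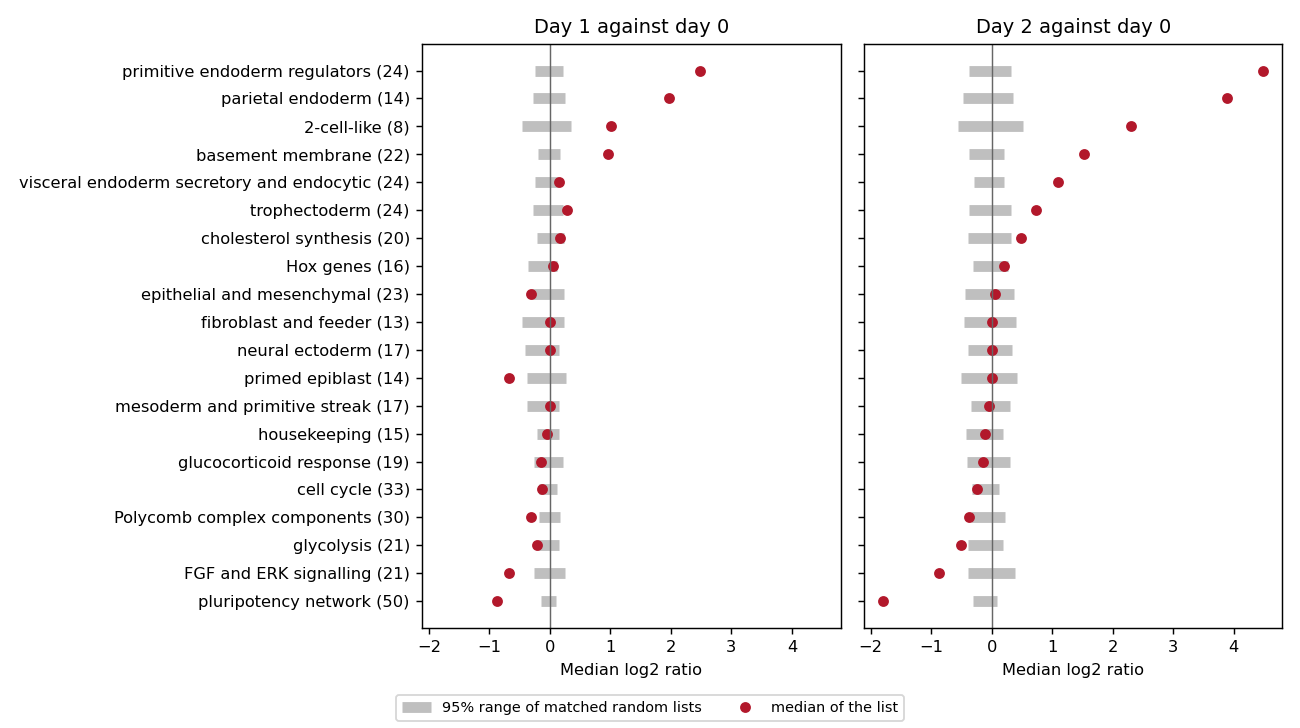
Median log2 ratio of each of the 20 gene lists (red points, number of measured genes in brackets) on day 1 and on day 2 against day 0, with the central 95% range of 10000 matched random lists as grey bars. Primitive endoderm regulators lay at 2.48 and 4.49 and pluripotency genes at -0.87 and -1.79, while housekeeping genes lay at -0.04 and -0.11 (0.0595 and 0.0246 with quantile normalization).

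Polycomb components, the subunits of chromatin repressor complexes, differed in both directions. On day 2, 5 of 30 were higher and 8 lower, with a median of -0.38 (percentile 1.48; -0.17 with means over probe sets), and on day 1, 3 were higher and 3 lower, with a median of -0.30 (percentile 0.05). The catalytic subunits of the first complex were within 2-fold of day 0: Ring1 read 366, 590.4 and 453, and Rnf2 (Ring1B) read 3830.2, 3337 and 2666. Phc1 was 9.51-fold lower on day 2, while Bmi1 was 4.79-fold and Yaf2 4.89-fold higher. Of the second complex, Ezh2 (log2 ratio -1.01), Eed (-1.41) and Jarid2 (-2.05) were lower and Suz12 stood at -0.96.

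Epithelial and mesenchymal genes had a median of -0.31 on day 1 (percentile 2.01, 7 of 23 higher and 7 lower) and 0.05 on day 2 (percentile 71.0, 9 higher and 6 lower). The claudin Cldn7 was 9.98-fold higher on day 2, whereas E-cadherin (Cdh1) had a log2 ratio of -1.08. With the floor at the 60th percentile the day 1 median was 0.00. Cell cycle genes had medians of -0.13 (percentile 8.93, 1 of 33 higher and 4 lower) and -0.24 (percentile 16.9, 5 higher and 6 lower). Cdk6 was 5.18-fold and cyclin D3 (Ccnd3) 4.18-fold lower on day 2 (log2 ratio -0.92 for Ccnd3 as a mean over probe sets), and the inhibitor Cdkn1a read 494, 202 and 1978 on the 3 days.

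Glycolysis genes had medians of -0.21 (percentile 1.97, 0 of 21 higher and 3 lower) and -0.51 (percentile 0.25, 2 higher and 5 lower). Pdk1 was 7.08-fold, Ldhb 5.63-fold and Pfkp 4.84-fold lower on day 2. Cholesterol synthesis genes had medians of 0.17 (percentile 92.6, 2 of 20 higher and 0 lower) and 0.48 (percentile 99.5, 4 higher and 1 lower; 0.76 with unspecific probe sets left out). The cholesterol transfer protein Stard4 was 3.03-fold and Hsd17b7 2.85-fold higher (log2 ratio 0.69 for Hsd17b7 as a mean over probe sets), and Pmvk was 2.27-fold lower. Glucocorticoid response genes, listed because the inducer is a glucocorticoid, had medians of -0.15 on both days (percentiles 16.5 and 38.2). Of 19, 0 were higher and 4 lower on day 1, and 2 were higher and 5 lower on day 2. Fkbp5, a common glucocorticoid target, read 3375, 1284 and 786, while Angptl4 was 7.00-fold and Pdk4 2.69-fold lower on day 2. The Angptl4 value came from an unspecific probe set, and the specific one was at the floor on each array, so it could not show a difference. Pdk4 had a log2 ratio of -0.54 with the floor at the 60th percentile.

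Of 20 listed 2-cell-like genes, which mark a rare ES cell state, only 8 had a probe set annotated to them alone, and all 8 were measured. Of these 8, 4 were higher on day 1 and 6 on day 2, with 0 lower and medians of 1.01 and 2.30 (percentile 100 on both days). The other listed genes could not be read here. Usp17la, from a family with near-identical copies, had a log2 ratio of 3.32 on day 2, and Zfp352 was 5.84-fold and Arg2 5.94-fold higher. The medians were 0.00 and 1.02 with the floor at the 60th percentile. Of 13 measured fibroblast genes, markers of feeder cells that such cultures can hold, 0 were higher and 1 lower on day 1, and 1 was higher and 1 lower on day 2, with medians of 0.00. Thy1 was at least 7.80-fold lower on day 2, Twist1, the higher gene, was at least 2.08-fold higher, and Col1a1, Col3a1 and Postn were at the floor on each array. The Twist1 difference was under 2-fold with loess scaling, with the receptors' floor (log2 ratio 0.68) and with the floor at the 60th percentile (0.00). The housekeeping list had medians of -0.04 and -0.11 (percentiles 53.7 and 64.7) and means of 0.08 and 0.06, and the medians were above 0 with quantile normalization (0.0595 and 0.0246) and with loess scaling (0.0027 and 0.103). Of its 15 genes, B2m (7.65-fold) and Gusb (2.34-fold) were higher and the transferrin receptor Tfrc (3.10-fold) lower on day 2.

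On day 2, the probe sets of a gene had the same sign in 722 of 832 higher and 541 of 629 lower genes that had several above the floor. Simulated arrays with no change gave a mean of 116 higher and 115 lower genes. A 3-fold threshold left 720 higher and 540 lower.

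The third comparison, day 2 against day 1, asks what differed between the later days. The calcium-binding protein S100g, which had the highest ratio, read 3998 on day 2 and was at the floor before, at least 74.0-fold higher, the visceral endoderm gene Ttr was at least 54.4-fold higher, and the selenium carrier Selenop was 31.6-fold higher. Pluripotency genes were again dimmer, with 17 of 50 lower and 0 higher, and a median log2 ratio of -0.67 (percentile 0). In all, 756 genes were at least 2-fold higher and 494 lower of 13468 compared.

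Endoderm lists were higher on day 2 than on day 1, with medians of 1.31 for parietal (8 of 14 higher, 1 lower), 0.78 for visceral (11 of 24 higher, 0 lower), 0.68 for primitive endoderm regulators (10 of 24 higher, 2 lower) and 0.57 for basement membrane (5 of 22 higher, 2 lower), each at percentile 100. With the floor at the 60th percentile the visceral median was 0.43 and the parietal one 0.95, and at the 25th the visceral one was 1.08. Gata6 differed by a log2 ratio of 0.12. The hypoxia-related factor Epas1 was 18.4-fold higher on day 2 than on day 1, having been 4.04-fold lower on day 1 than on day 0. Others among the 10 highest were the small heat shock protein Cryab (19.2-fold), Nxf7 (log2 ratio of at least 4.32), the activin antagonist Fst (16.9-fold), Cldn6 (15.4-fold), Hdc (at least 14.7-fold) and Timp3 (at least 14.4-fold). The Cryab signal came from unspecific probe sets (log2 ratios from 4.26 to 5.20). Its specific one was at the floor on each array and could not show a difference. Cyp4f14 was lowest: it read 1006 on day 1 and was at the floor on the other days, a difference of at least 18.6-fold. Shkbp1 was 6.84-fold lower after 11461 on day 1, and Rsph1 (at least 9.02-fold), Tgfbi (7.94-fold), Gng2 (7.34-fold), Sapcd1 (at least 6.56-fold), Apobec2 (at least 6.48-fold), Acacb (at least 6.30-fold) and Gpr4 (at least 6.22-fold) were also lower. The probe sets of a gene had the same sign in 294 of 333 higher and 169 of 207 lower genes. At the 25th percentile floor the counts were 1336 higher and 912 lower, and at the 60th 440 and 272.

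The differences on day 1 and day 2, both against day 0, were then set side by side over 14257 genes. Of the genes higher on day 1, 78.8% were also higher on day 2, and of those lower, 70.9% were also lower. This gave 643 genes higher on both days and 635 lower on both, against 87.7 and 87.8 for independent lists and means of 21.8 and 32.2 in arrays simulated with no change. Opposite directions were seen in 2 genes (higher, then lower) and 9 genes (lower, then higher), Epas1 and Cdkn1a among the latter. A further 880 genes were higher and 762 lower on day 2 while within 2-fold on day 1. Across genes, which are not independent replicates, Pearson's r was 0.79 and Spearman's rho 0.72. The simulated means were 0.50 and 0.47, since both ratios use the same day 0 array. The covariance was 0.594 against 0.0666 simulated, a difference of 0.527. Part of the overlap may come from the shared array, which could not be split.

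**Figure D3:**
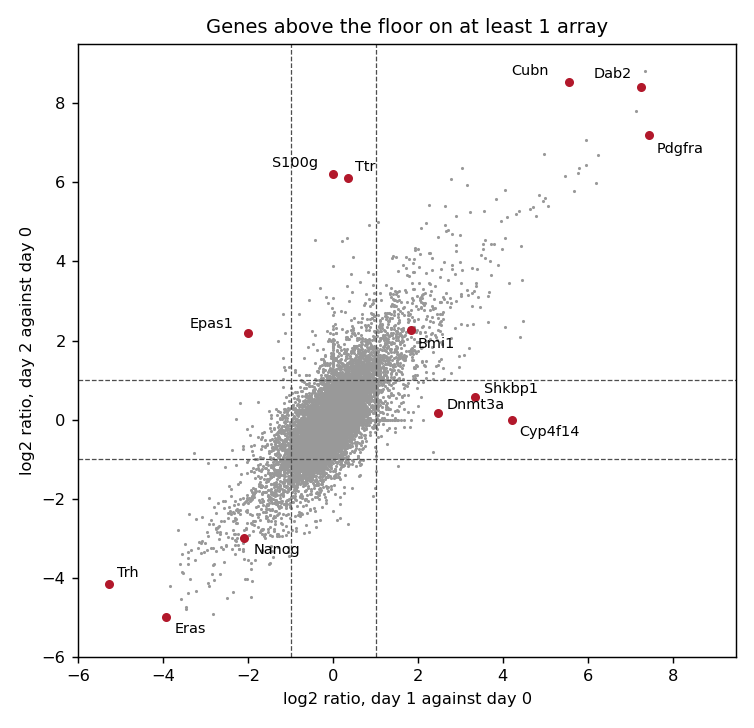
Each grey point is 1 of 14257 genes, with its log2 ratio of day 1 against day 0 on the horizontal axis and of day 2 against day 0 on the vertical axis, and dashed lines mark 2-fold differences. Named genes are in red: Ttr lies at 0.34 on the horizontal and 6.11 on the vertical axis and S100g at 0.00 and 6.21, whereas Dnmt3a lies at 2.46 and 0.17.

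A group of 98 genes was at least 2-fold higher on day 1 than on both other days, and 85 were at least 2-fold lower. The simulated means were 32.4 and 20.2, with highest values of 49 and 30. The DNA methyltransferase Dnmt3a read 969.6, 5334 and 1094 on the 3 days, and Bcl2l11, a regulator of cell death, read 1388, 4388 and 1219. On the lower side, Igfbp4 read 405, 89.1 and 546. Other probe sets of these genes, not used to choose them, went the same way in 58 of 72 cases for the higher genes and in 29 of 66 for the lower ones.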

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

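The alternatives for the 5 lists chosen after the data were seen, the secretory and ribosomal ones among them, were added then too, and no others were. The cause was not tested for the values that moved. Most named genes had been chosen for wide differences, so kept signs were likely beforehand and say little about other genes. Among the named genes direction held widely: of 2199 alternative values for those that differed at least 2-fold, 2190 kept their sign, 0 took the opposite one and 2142 were still 2-fold. The 57 that were not came mostly from the floor at the 60th percentile (25) and the mean over probe sets (15), and 6, of Angptl4, Cpsf4l and Cryab, from leaving out unspecific probe sets. Angptl4 and Cryab had no specific probe set above the floor. That setting could not give a value for 17 named genes, Sox17, Serpinh1, Eras and Ttr among them. The 4 other scalings moved no count by over 1.5 times and no median of the 20 lists fixed beforehand beyond its spread. Of 150 alternative medians of the later 5 lists, 146 stayed within it, and the 4 that did not were of ribosomal proteins under quantile normalization or loess scaling.

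The counts depended on the floor and threshold. For day 1 against day 0 they were 1256 higher and 1618 lower at the 25th percentile floor, 539 and 517 at the 60th, 346 and 288 at 3-fold, and 1421 lower with a pseudocount in place of the floor. For day 2 against day 0 they were 720 and 540 at 3-fold. For day 2 against day 1 they were 1336 and 912 at the 25th percentile, 440 and 272 at the 60th, 1169 and 792 with the pseudocount, and 228 and 112 at 3-fold. The other 49 alternative counts lay within 1.5 times.

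Of the alternative medians of the 20 lists, 566 moved by less than the spread, 33 by more, and 1 by more with a change of sign: trophectoderm on day 1, from 0.28 to -0.069 with specific probe sets. A further 15, of the housekeeping and primed epiblast lists, changed sign within the spread and were at most 0.103 in size. Primitive endoderm regulators had medians of 1.78 (day 1) and 3.18 (day 2) at the 60th percentile floor, and on day 2 of 3.43 as means over probe sets and 4.05 with specific ones. Parietal endoderm genes on day 2 had 3.28 at the 60th percentile and 2.73 as means over probe sets. Pluripotency genes on day 2 against day 1 had -0.47 at the 60th percentile. The correlations across genes stayed from 0.736 to 0.812 (Pearson) and from 0.674 to 0.760 (Spearman). On each array 39.3% to 41.0% of probe sets lay under the floor, where values have no order. No paired analysis was possible because each day had 1 array.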

Other observations

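The tests of explanations in this part, and the gene groups in its opening paragraphs, were chosen only after the values were seen, although the housekeeping, pluripotency and glucocorticoid lists used in them had been fixed beforehand.

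Of 23 measured genes of the unfolded protein response, which adjusts protein folding capacity, 9 were higher and 0 lower on day 1, and 15 higher and 1 lower on day 2, with median log2 ratios of 0.89 and 1.15 (percentile 100 on both days). The chaperone Hspa5 (BiP) read 8106, 21949 and 24014 on the 3 days, and the membrane-bound factor Creb3l2 read 84.4, 978 and 1826. The stress factors Atf4 (log2 ratio -1.08 on day 2) and Ddit3 (-0.38) were not higher. Most of 68 secretory pathway genes were within 2-fold, 62 on day 1 (5 higher, 1 lower) and 41 on day 2 (27 higher, 0 lower), with medians of 0.48 and 0.85 (percentile 100). The higher ones on day 2 included the coat subunit Sec24d (log2 ratio 2.71) and Surf4 (2.46).

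Ribosome biogenesis genes had medians of -0.20 (percentile 0.04) and -0.52 (percentile 0), and 7 of 60 were lower and 1 higher on day 2. Ribosomal protein genes had -0.10 and -0.20 (percentiles 16.8 and 35.5), with 0 of 48 higher and 1 lower on day 2, but 0.0081 and -0.023 with quantile normalization and -0.025 and -0.0063 with loess scaling, so no direction is given for them. Of 13 Hedgehog genes, 2 were higher and 4 lower on day 2, with a median of -0.04 (percentile 48.5) and a mean of -0.34. The effector Gli1 had a log2 ratio of -3.08, with day 2 at the floor, while the ligand Ihh had 4.05, with day 0 at the floor. B2m, the light chain of MHC class I, was 7.65-fold higher on day 2, and the heavy chains H2-K1 (814, 1008 and 2689.6) and H2-D1 (1259, 2322 and 4141) also read brighter, on unspecific probe sets. Of the 9160 unnamed probe sets, 348 were higher and 281 lower on day 2.

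Genes at least 2-fold higher (98) or lower (85) on day 1 than on both other days were weighed first. For the higher ones, noise of single probe sets is argued against only for the 42 of 98 genes with another probe set above the floor. Their other probe sets went the same way in 80.6% of 72 cases (95% exact interval 69.5% to 88.9%), where noise would give about 1 in 3. The interval takes probe sets as independent, although some share a gene. The remaining higher genes could not be tested this way. Arrays simulated with no change gave 32.4 higher genes of this kind on average and 49 at most, so noise may account for a part of them. For the lower ones the share was 43.9% of 66 (31.7% to 56.7%), an interval that includes 1 in 3. A probe set at the floor on day 1 and on another day counted as going the other way, so noise would give less than 1 in 3 here. The share therefore cannot decide, and it is not comparable with that of the higher genes. Noise simulated with no change gave 20.2 lower genes of this kind on average and 30 at most, so it may account for a part of the 85 that was not settled. Both directions pooled gave 63.0%, and they were separated after the pooled value was seen. A scaling error of the day 1 array had no independent test. Each array had been scaled to the same trimmed mean, which removes a common factor, before the housekeeping median log2 ratio of -0.045 was taken. A common factor would move all genes the same way, so it alone cannot give both the 98 higher and the 85 lower genes. Some of these genes also differed at least 2-fold between day 2 and day 0, such as Cpn1 (log2 ratio 2.48) and Trh (-4.17). Others, such as Dnmt3a (0.17), did not. With 1 day 1 array, a difference of that culture or hybridisation and a response of the cells cannot be told apart.

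The split of the pluripotency list on day 2, with 33 genes lower and 17 within 2-fold, was weighed next. Undifferentiated cells left in the culture would have to make up at least 50% of it to hold the 17 genes within 2-fold, and 22 list genes were at least 4-fold lower, with Eras at 3.16% of day 0, which such a share would not allow. Saturated probe sets are argued against for some of the 17 genes. Of the 17, 5 (29.4%) read brighter on a later day than on day 0 by more than 2 SD of the probe set error. They were Klf4, Sall4, Lin28a, Fbxo15 and Dnmt3l, which thus were not at a ceiling on day 0. The other 12 did not read brighter by that margin, which alone is no sign of a ceiling. Among them, Dppa3 (125), Tet2 (1159), Il6st (1229), Lifr (2103), Stat3 (2997), Tbx3 (3518) and Socs3 (4348) read far below the day 0 maximum of 53581. An array-wide ceiling is argued against for these, while lower ceilings of single probe sets were not tested. Saturation stays open for brighter ones, such as Dppa5a (40759). RNA that outlasts its transcription is also open: the 17 genes had a median log2 ratio of -0.16 on day 2 against day 1 (95% interval -0.31 to 0.20), and 7 of them were above day 0 on day 2. Continued expression of these genes in endoderm may be another explanation and was not tested.

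The broad differences on day 1 were weighed against a response to dexamethasone itself. If the day 0 cells had no dexamethasone, induction of common glucocorticoid targets is argued against, as 0 of 19 such genes were at least 2-fold higher. Their median ranked at percentile 16.5 of matched lists. Whether the day 0 cells lacked dexamethasone is not given in the sources used here. Had they received it too, this comparison could not show an induction. Other effects of dexamethasone may remain, since cells given it without the Gata6 construct were not analysed here.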
